A study of Trichoderma harzianum and Trichoderma virens and Trichoderma reesei with 24 samples.

How the data were processed

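RNA from mycelium of 4 Trichoderma strains was measured on 1-colour (Cy3) oligonucleotide arrays. Per the labels' protocols, mycelium was grown in the dark for 48 h in minimal medium with 2% glucose (28 °C, shaken at 200 rpm), washed, and moved into boxes with tomato plants that were 2 weeks old and grown over liquid medium (30 seeds and 100 mL per box). Cultures with plants were kept for 20 h at 25 °C and 80 rpm. Mycelium, including that washed off the roots, was then collected and freeze-dried, and each strain was also cultured without plants. The labels give 40 µg of RNA per set of 3 arrays and do not say whether the 3 arrays of a group came from separate cultures. The p-values of comparisons between arrays therefore measure only the spread between these arrays, which may be technical. Those of overlaps, of the order of rises and of neighbouring models take probe sets or gene models as units. These units are not independent.

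The 24 arrays formed 8 groups of 3, 1 for each strain with and without tomato. The groups were taken from the labels on culture conditions. On the 3 arrays of strain T7 without plants, the strain field and the organism field named T34 and T. harzianum, while the title, the culture conditions and the design text named T7; these arrays were kept as T7. Their log2 values correlated with those of the T7 arrays with tomato at r = 0.965 to 0.980 and with the T34 arrays at r = 0.461 to 0.501, across probe sets. The organism field gave T. reesei for the arrays of strain T6, which the design text calls T. parareesei. Replicate numbers followed the order of deposit and paired no arrays.

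The deposited values were intensities on a linear scale. Per the submitters' processing notes the authors used RMA; the software, its version and which arrays were normalized together are not given in the sources used here. A deposited per-array table of RMA intensity was the main input, after log2. A second deposited per-array table held the mean perfect-match probe intensity of each probe set, without normalization between arrays, per the file headers and values. The deposited series table was equal to the RMA table in every cell (0 cells differed by over 0.001), so it is not an independent alternative. Each array held 34138 probe sets, of which 34027 had 11 probes. A column of the files put them into 3 classes, SPP (13392 probe sets), REESEI (9109) and VIRENS (11637); probe sets of SPP carry 1 of 11 codes in their names. Control probe sets were not seen in the tables.

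The files pair the probe sets with gene model numbers and not with gene names or product descriptions, and 0 of the identifiers matched the reference gene table, which covers T. harzianum. The 23 gene lists fixed before the data were examined, which included tomato transcripts, and the reference genes could therefore not be matched, and no list test was run. Under the rule fixed for that case, at most 2 probe sets that rose and 2 that fell were named for each strain: those with the largest log2 change among probe sets that passed the threshold and whose 3 tomato arrays all lay on 1 side of the 3 other arrays. The same number was applied to probe sets called in most strains, and the 2 probe sets with the smallest interaction p were named.

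Within each strain the 3 arrays with tomato were compared with the 3 without by limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all 34138 probe sets and a threshold of 0.05. Differences in response among strains were tested by a limma F-test of the 3 interaction terms over all 24 arrays with 8 group means, and by the contrast of each of 6 strain pairs. Overlaps of calls were tested by Fisher's exact test, two-sided, per direction, with adjustment over 12 tests. These tests were fixed before the data were examined. On simulated data with 200 changed probe sets per strain, drawn with each probe set's own spread, the test recovered 48% of log2 changes of 1 in T34, 16% in T7, 64% in T87 and 36% in T6, and 100%, 50%, 96% and 94% of changes of 2. The share of false calls was 3.05%, 3.49%, 2.96% and 7.94%. The number of arrays limits the precision.

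Alternatives fixed in advance covered the unnormalized table with quantile normalization, with and without normexp background correction (offset 50, values under 1 set to 1 where no correction was made), a second quantile normalization, median centring, a filter on dim probe sets, 1 fit of all 24 arrays, other estimates of spread, array weights, other thresholds and leaving out each array. Chosen after seeing the data were a count without probe sets over 8 times brighter (mean over 6 arrays) in another strain than in the strain tested, the grouping of probe sets into near background (under 90.51) and bright (over 4096), and the comparison of overlaps among probe sets over 256 in both strains. Figures were drawn with matplotlib 3.10.9. Intervals of the ratios between 2 median percentages came from 10000 bootstrap resamples of probe sets, chosen after seeing the data.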

Results

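The series asked how 4 Trichoderma strains, fungi used as biological control agents, change their transcripts early in contact with tomato plants. Strains T34 (T. harzianum), T7 (T. hamatum), T87 (T. virens) and T6 (T. parareesei) were each measured after 20 h with and without plants, on 3 arrays per group. Median unnormalized intensities lay between 199 and 471 per array. Within a group, log2 values of arrays correlated at r = 0.992 to 0.996 in T34, 0.965 to 0.982 in T7, 0.990 to 0.997 in T87 and 0.990 to 0.995 in T6, across probe sets. The median residual SD was 0.40 on the log2 scale in T7, against 0.21 in T34, 0.21 in T87 and 0.23 in T6.

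Each strain lit its own part of the array. The VIRENS class had a median intensity of 605 ± 89.1 (SD, n = 3) in T87 without plants, against 45.8 ± 0.166 in T34 and 25.0 ± 0.576 in T6. The REESEI class had a median of 1565 ± 127 in T6 without plants and 20.5 ± 1.48 in T87. Within the SPP class, codes T34 and S34 were brightest in T34 (medians of 4786 and 4696 without plants), codes T53 and TP1 in T7 (3533 and 1462), and codes T52 and T59 in T87 (2453 and 2500). Between 26.7% and 34.8% of probe sets exceeded 256 on each array.

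**Figure D1:**
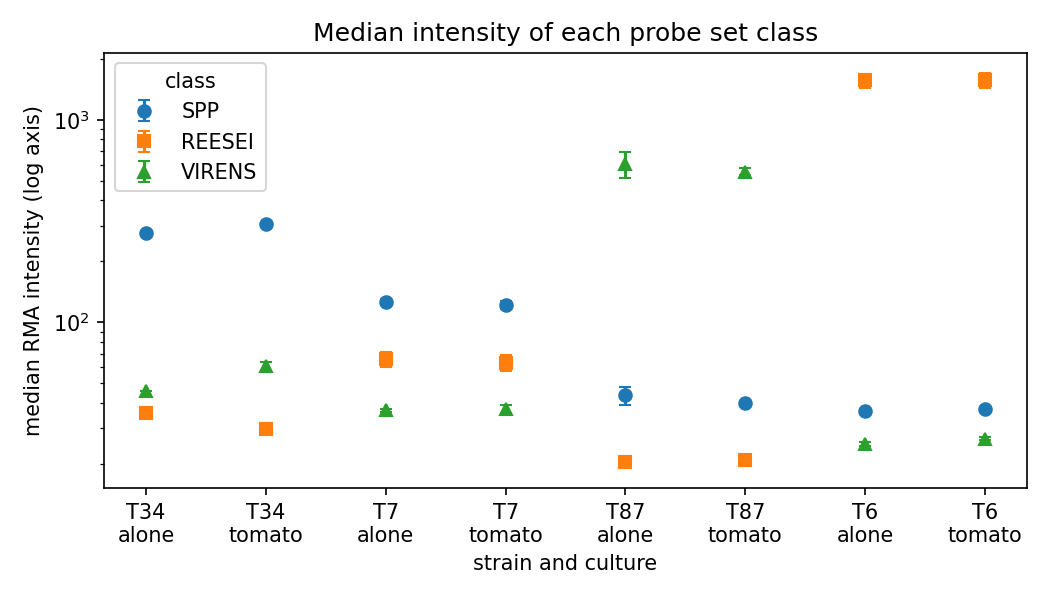
Median RMA intensity (log axis) of the 3 probe set classes in the 8 groups; points are means of 3 array medians and bars are SD. The VIRENS class stands at 605 in T87 without plants and the REESEI class at 1565 in T6 without plants.

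In T34, 5644 of 34138 probe sets changed with tomato, 3258 higher and 2386 lower (limma with Benjamini-Hochberg adjustment). Of these 1616 changed at least 2-fold, 1350 of them higher; on the unnormalized table after quantile normalization 451 rose at least 2-fold. In the SPP class, codes T34 and S34 had 689 and 75 higher against 366 and 26 lower. The VIRENS class, which is dim in this strain, had 1718 higher and 586 lower, and codes T52 and T59 had 253 and 271 higher against 53 and 44 lower. The REESEI class, also dim here, had 40 higher and 699 lower, and codes TP1, T53, T11, TST and TH2 had 9, 12, 6, 5 and 21 higher against 111, 92, 75, 73 and 68 lower. Of the 5644 changed probe sets 2761 were over 8 times brighter in another strain, and 1842 of those rose. That is 48.9% of the changed probe sets, against 45.3% of all 34138.

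On RMA values, the T34 probe sets picked by the rule for rises were VIRENS gene models, with levels near background without plants, so that the size of their change depends on the background treatment. TRIVE_51487 rose from an intensity of 12 to 1277 (log2 change 6.73, SE 0.20, n = 3, limma adjusted p = 3.2e-13), and its level in T87 was 36700 without plants and 32240 with them. TRIVE_111106 rose from 19.3 to 1629 (log2 6.40, SE 0.19, limma adjusted p = 3.2e-13), with 17820 and 19930 in T87. On the unnormalized table after quantile normalization their log2 changes were 3.63 and 4.84, and another probe set reached 5.67. Of probe sets that fell, L15T34P120R10728 went from 1062 to 68.3 (log2 -3.96, SE 0.26, limma adjusted p = 5.81e-09) and L21T78P017R01558 from 295 to 28.0 (log2 -3.39, SE 0.34, limma adjusted p = 1.11e-06).

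The rise in T34 followed the level of a probe set in T87. Among 648 probe sets near background in T34 without plants and bright in T87, the median log2 change was 2.27, and 98.5% were higher by over 0.5. The median was 2.44, 2.27 and 2.20 on the 3 tomato arrays. Among probe sets near background in T34 and bright in T6 the median was -0.22 (1173 probe sets), and among those bright in T7 it was -0.11 (711). These are RMA values. On unnormalized intensities, each array centred on its median, the medians were 0.52 for the T87-bright, 0.00 for the T6-bright and 0.04 for the T7-bright probe sets. On RMA values the median increment was 1.59% of the T87 level. The size depends on how probe sets are chosen, and other choices were made after seeing the data: 94 T87-bright probe sets near background with tomato had a median of -1.70 in the cultures without plants against those with tomato, and 1610 T87-bright probe sets over 8 times brighter in T87 by the mean of 6 arrays had a median rise of 0.79. With all probe sets over 8 times brighter in another strain left out, a choice made after seeing the data, 2853 of 18676 changed in T34 in a new fit, 1418 higher and 1435 lower. A fit of all 24 arrays called 2889 in T34.

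**Figure D2:**
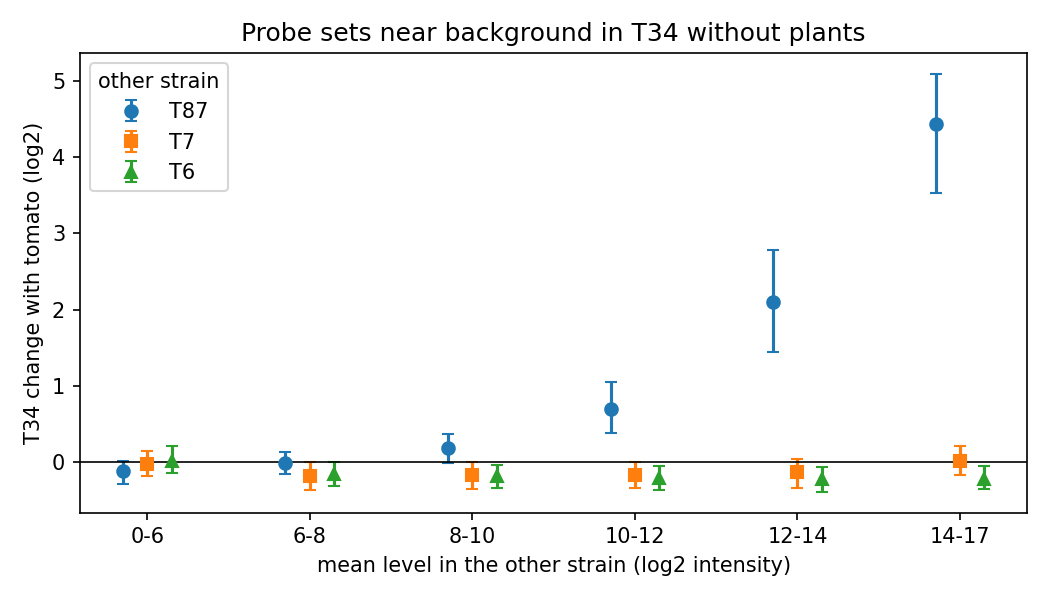
Log2 change with tomato in T34, on RMA values, of probe sets near background in T34 without plants, against their mean log2 intensity in T87, T7 or T6. Points are medians and bars span the quartiles. The median rises to 4.43 in the brightest T87 bin and lies at 0.02 and -0.22 in the brightest T7 and T6 bins.

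In T7, 126 probe sets changed, 81 higher and 45 lower (limma with Benjamini-Hochberg adjustment), and 2603 had an unadjusted p under 0.05. The balance turned with the processing, to 364 higher and 392 lower on the unnormalized table after quantile normalization and 731 and 769 in a fit of all 24 arrays. Most were in the SPP class, with 63 higher and 44 lower. L92S34P002R00159 rose from 34.1 to 3590 (log2 6.72, SE 0.36, limma adjusted p = 9.06e-06, n = 3) and L92S34P003R00241 from 21.3 to 1869 (log2 6.46, SE 0.35, limma adjusted p = 9.06e-06). On the unnormalized table after quantile normalization these log2 changes were 2.80 and 1.62. Both probe sets belong to the group of 8 described below, for which tomato RNA and fungal transcripts cannot be told apart. L13T11P094R08853 went from 868 to 64.4 (log2 -3.75, SE 0.44, limma adjusted p = 0.00531) and L12T11P105R09920 from 1579 to 133 (log2 -3.57, SE 0.62, limma adjusted p = 0.0377). These falls were -1.95 and -0.90 on the unnormalized table after quantile normalization. The count rested on single arrays and on the spread model: it was 22 to 176 with 1 array left out, 7 without an intensity trend and 1500 in a fit of all 24 arrays. L12T11P105R09920 lost its call without T7 array 1, 2 or 3 of the cultures without plants or array 1 with tomato (limma adjusted p = 0.171, 0.165, 0.117 and 0.107), and L13T11P094R08853 without array 1 of the cultures without plants (0.0523).

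In T87, 2533 probe sets changed, 1094 higher and 1439 lower (limma with Benjamini-Hochberg adjustment), and 986 changed at least 2-fold, 485 higher and 501 lower. On the unnormalized table after quantile normalization 234 rose and 185 fell at least 2-fold. In the VIRENS class 667 were higher and 597 lower, and among those changed at least 2-fold 301 were higher and 79 lower. TRIVE_29271 rose from 80.6 to 6334 (log2 6.30, SE 0.18, limma adjusted p = 4.13e-10, n = 3) and TRIVE_69988 from 51.8 to 2915 (log2 5.82, SE 0.24, limma adjusted p = 9.5e-09). S34C31 went from 2294 to 131 (log2 -4.13, SE 0.18, limma adjusted p = 1.81e-08) and T34C744 from 1667 to 103 (log2 -4.01, SE 0.19, limma adjusted p = 2.73e-08). Both of these were over 8 times brighter in another strain, and on the unnormalized table after quantile normalization their log2 changes were -2.48 and -1.61.

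Codes T34 and S34, dim in T87, had 460 and 49 probe sets lower with tomato against 139 and 14 higher. Code T34 leaned the same way in T6, with 95 lower and 15 higher, and in T7, with 17 and 4. Code S34 had 13 lower and 5 higher in T6 but leaned the other way in T7, with 2 lower and 9 higher. Among 873 probe sets near background in T87 with tomato and bright in T34, the cultures without plants were higher by a median log2 of 0.62, against -0.05 for 1584 probe sets bright in T6. Chosen instead as near background without plants, 712 T34-bright probe sets had a median log2 difference with tomato of -0.40, against 0.06 for 1628 bright in T6. On unnormalized intensities, each array centred on its median, the first choice gave 0.14 for T34-bright and -0.02 for T6-bright probe sets. The second gave -0.08 and 0.02. Among 1846 T34-bright probe sets over 8 times brighter in T34 by the mean of 6 arrays, the cultures without plants were higher by a median of 0.15. Of T34-bright probe sets near background with tomato in T7 or T6, those cultures without plants were higher by a median of 0.16 and 0.19. Of the 2533 changed probe sets, 1751 were not over 8 times brighter in another strain, 920 of them higher and 831 lower. A new fit of such probe sets alone called 2509 of 19382, 1159 higher and 1350 lower, and held all 1751. The count in T87 was 1390 to 5778 with 1 array left out, the highest without array 3 of the cultures without plants; it was 1605 without array 1 of those cultures and 1390, 1663 and 1412 without tomato arrays 1, 2 and 3. It was 4056 on the unnormalized table after quantile normalization and 4158 with array weights.

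In T6, 902 probe sets changed, 413 higher and 489 lower (limma with Benjamini-Hochberg adjustment). The balance turned with the scaling: 45.8% were higher on RMA values, 37.2% after median centring and 62.5% on the unnormalized table after quantile normalization. The REESEI class held 498 of them, 266 higher and 232 lower. L92S34P002R00159 rose from 17.2 to 110 (log2 2.69, SE 0.20, limma adjusted p = 2.96e-05, n = 3) and TRIRE2_71072 from 46.9 to 274 (log2 2.55, SE 0.23, limma adjusted p = 0.000127). TRIRE2_30759 went from 12780 to 1779 (log2 -2.85, SE 0.16, limma adjusted p = 2.21e-06) and L22T11P131R11766 from 203 to 29.2 (log2 -2.80, SE 0.32, limma adjusted p = 0.000615). L92S34P002R00159 and L22T11P131R11766 were over 8 times brighter in another strain, and on the unnormalized table after quantile normalization their log2 changes were 0.56 and -1.10. Of the 902, 608 were not over 8 times brighter in another strain, 329 higher and 279 lower; a new fit of such probe sets alone called 898 of 18994, 475 higher and 423 lower. The count was 377 and 303 without array 1 or 3 of the cultures without plants, 330 without tomato array 3, and 1998 with array weights.

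**Figure D3:**
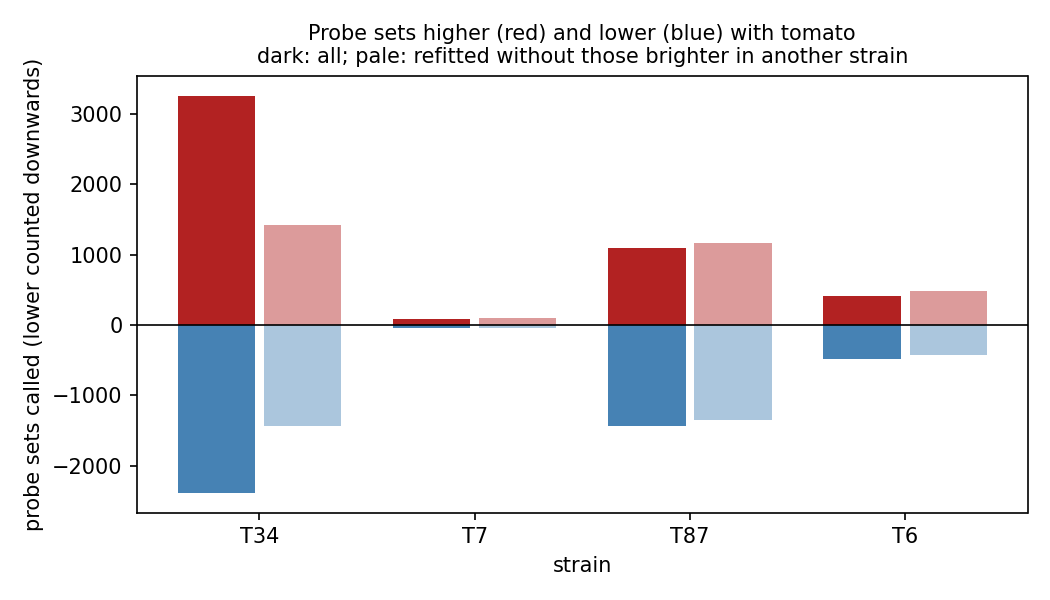
Probe sets called higher (upwards) and lower (downwards) with tomato in each strain; dark bars are the fit of all probe sets and pale bars a new fit, with its own spread and adjustment, without those over 8 times brighter in another strain. In T34 the higher calls are 3258 and 1418, and in T87 1094 and 1159.

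The response differed among strains at 4727 probe sets (limma F-test of 3 interaction terms, Benjamini-Hochberg), and at 472 of 9970 once probe sets over 8 times brighter in another strain were left out for any strain. This fit takes 1 spread per probe set from all strains, though the median residual SD was 0.40 in T7 and 0.21 to 0.23 elsewhere. Under that shared spread T7 had 1500 calls against 126 when fitted alone, and T34 2889 against 5644. Interaction calls that involve T7 may therefore understate its error. L50TH2P003R00207 had the smallest interaction p (limma adjusted p = 1.59e-16), with a log2 change of 5.31 in T34, 0.20 in T7, 0.08 in T87 and 0.00 in T6. It rose from 15.49 to 616 in T34. Without and with tomato it lay at 13.07 and 14.98 in T7, 10.03 and 10.58 in T87, and 12 and 12 in T6. These levels in T7, T87 and T6 are under the near-background limit of 90.51, so the small changes there may reflect lack of signal. For T87 and T6 it was over 8 times brighter in another strain. TRIVE_51487 came next (limma adjusted p = 5.16e-15) and was over 8 times brighter in T87 than in T34, T7 and T6. The count was 9422 on the unnormalized table after quantile normalization, 9359 with array weights and 7261 without tomato array 3 of T7.

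Calls of 1 direction were mostly in 1 strain: 3974 probe sets were called higher in exactly 1 strain, 413 in 2, 10 in 3 and 4 in 4. The counts for lower calls were 3811, 265, 6 and 0. These counts do not measure how specific responses are to a strain, because each strain lit only part of the array. Per strain, 43.2% to 48.4% of probe sets were over 8 times brighter in another strain. Power also differed, with 16% of simulated log2 changes of 1 recovered in T7 and 64% in T87. L92S34P002R00159 and L92S34P003R00241 rose in all 4 strains, by log2 5.91 and 5.39 in T34, 1.80 and 1.15 in T87 and 2.69 and 1.75 in T6. With tomato they reached only 56.1 and 27.3 in T87, under the near-background limit of 90.51, and 110 and 58.8 in T6. Both belong to the group of 8 described below, for which tomato RNA and fungal transcripts cannot be told apart. T78C49 fell in T34, T87 and T6 (log2 -0.91, -1.47 and -1.85), and T34C437 fell in T7, T87 and T6 (log2 -2.48, -1.76 and -1.03). Both were over 8 times brighter in T34 than in T7, T87 and T6: without plants T34C437 was at 11770 in T34 and T78C49 at 2758.

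T34 and T87 shared the most calls, with 369 probe sets higher in both against 104 expected from independent lists. Lower in both were 172 against 101 (Fisher's exact test, adjusted p = 5.91e-111 for higher and 1.67e-11 for lower), and 292 were called in opposite directions. The test takes probe sets as independent, which they are not, so the p-values of overlaps may be too small. Among 4826 probe sets over 256 in both and not over 8 times brighter elsewhere, 193 were called the same way and 18 in opposite ways, and 25 against 1 where both changed at least 2-fold. This restriction was chosen after seeing the data; with the intensity limit alone the counts were 271 and 33 of 6904. T34 and T7 shared 28 higher calls against 7.73 expected (Fisher's exact test, adjusted p = 2.05e-09) and 3 lower against 3.15 (adjusted p = 1.0). T7 and T87 shared 15 higher against 2.60 and 13 lower against 1.90 (adjusted p = 7.91e-08 and 6.24e-08). T7 and T6 shared 5 higher against 0.980 (adjusted p = 0.00523) and 2 lower against 0.645 (adjusted p = 0.181). T87 and T6 shared 64 lower against 20.6 (adjusted p = 6.35e-15) and 19 higher against 13.2 (adjusted p = 0.179). T34 and T6 shared 31 higher against 39.4 and 29 lower against 34.2 (adjusted p = 0.212 and 0.459), with 93 in opposite directions. Under the same restriction as for T34 and T87 (over 256 in both and not over 8 times brighter elsewhere), T87 and T6 shared 3 lower calls against 1.41 (adjusted p = 0.220), and T7 and T87 shared 0 lower against 0.230 (adjusted p = 1.0) and 8 higher against 0.721 (adjusted p = 5.29e-07). T34 and T7 then shared 7 higher calls against 2.06 (adjusted p = 0.00812), and T7 and T6 1 against 0.179 (adjusted p = 0.220). For T34 and T6 the balance turned, with 8 called the same way and 1 in opposite ways among 2348 (3 higher against 1.16 and 5 lower against 2.00, Fisher's exact test, adjusted p = 0.178 and 0.1005), and 13 against 6 with the intensity limit alone.

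A group of 8 probe sets, all with code S34 (of 325), had group mean intensities of at most 34.1 in every strain without plants. With tomato they were at least 4-fold higher in T34 and T7. On RMA values their log2 changes were 2.70 to 5.91 in T34 and 3.83 to 6.72 in T7, and on the unnormalized table after quantile normalization 0.65 to 3.18 and 0.47 to 2.80, where 8 and 6 of them passed the threshold. Their sizes depend on the background treatment. On RMA values the group means of all 8 were higher in T7 with tomato than in T34 with tomato. Single arrays did not all follow. Array 3 of T7 with tomato gave 72.4 for L92S34P001R00093, against 104 to 136 in T34 with tomato. For L92S34P006R00534 it gave 121, against 174 to 218. In T87, 3 rose, and in T6, 2 rose. The group was defined after seeing the data. It includes L92S34P002R00159, named above in T7, T6 and all 4 strains, and L92S34P003R00241, named in T7 and all 4 strains.

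**Figure D4:**
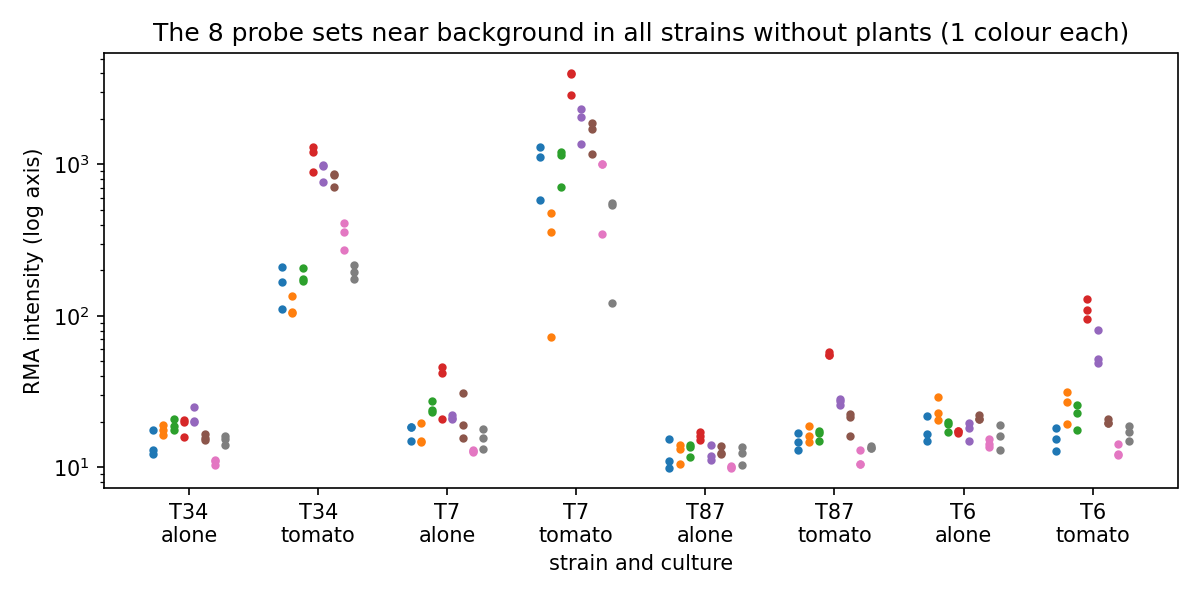
RMA intensity (log axis) of the 8 probe sets on each of 24 arrays; points are arrays and colours are probe sets. Without plants the group means stay at or under 34.1 in every strain.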

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

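The test of normalization by mean intensity, the relabelling of the interaction and the ratio of 2 percentages in T87 were set before their results were seen; the tests of excess, of selected induction and by ranks, the ratio in T34, the intervals and quartiles of both ratios and the splits of 6 arrays were chosen after.

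The response to tomato differed between strains by the interaction test at 4727 probe sets, and between T34 and T7 at 2585, T34 and T87 at 2558, T34 and T6 at 2495, T7 and T87 at 1539, T7 and T6 at 1175, and T87 and T6 at 1203 (limma, Benjamini-Hochberg). All use 1 spread per probe set over the 4 strains, which mixes T7 with strains of smaller spread. Each strain lit only part of the array, so a probe set that is dark in 1 strain can be called for lack of signal there. Without probe sets over 8 times brighter in another strain, for any strain, 472 of 9970 were called. The counts of strain pairs were not repeated that way. L50TH2P003R00207 (limma adjusted p = 1.59e-16) and TRIVE_51487 (limma adjusted p = 5.16e-15) had the smallest interaction p, and both are among the probe sets left out. Of 100 relabellings of the arrays within strains, 1, the real one, gave as many as 4727. The highest other gave 3238; the 6 relabellings that kept the T34 groups apart gave 1219 to 3238, and the 93 that mixed them gave up to 1364, so much of the count follows the T34 arrays. Within each strain, 1 of the 10 splits gave as many calls as the real one (5644 in T34, 126 in T7, 2533 in T87, 902 in T6), and the highest other gave 0, 0, 1 and 0; 10 splits are too few for a share under 0.05.

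In T34 with tomato, probe sets near background without plants were higher where T87 was bright, by 2.49 on the log2 scale more than T6-bright ones; this excess restates the pattern and supports no explanation. Of the members 98.5% were higher by over 0.5, against 0.426% of T6-bright and 2.25% of T7-bright probe sets chosen the same way. The choice alone therefore does not give this share. The test was chosen after the rise had been seen and its members lie near background, so induction of T34 transcripts is left open. Ranks were taken on the unnormalized intensities, each array centred on its median, with members chosen on RMA values. By these ranks 62.4% of T87-bright members had every tomato array above every other array. The share was 5.12% of T6-bright members and 5% by chance. This argues against normalization for members chosen as near background without plants, the only choice tested by ranks. The test set in advance, on the same centred intensities, did not decide, at 0.52 between the bounds of 0.3 and 0.6. Increments are given on RMA values, here over probe sets chosen by their mean of 6 arrays. The median increment was 1.15% of the T87 level at log2 levels of 12 to 14 and 1.65% at 14 to 17. The ratio was 1.42 (bootstrap interval 1.29 to 1.60 over probe sets, which are not independent), under the bound of 2 for RNA added in 1 proportion. Over 3522 probe sets near background in T34 without plants and over 256 in T87, the increment followed the T87 level (Spearman 0.797 without plants, 0.791 with tomato). With the T6 level the value was 0.171. Among 191 of them that changed at least 2-fold in T87 the T87 values were 0.663 and 0.536, a difference that was not tested. RNA of T87 or a close relative may account for the rises. Where it would have entered, and a response of T34 transcripts, stay open.

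In T87 without plants, probe sets near background with tomato were higher where T34 was bright, by 0.67 on the log2 scale more than T6-bright ones; this too restates the pattern, and the difference was smaller when probe sets were chosen as near background without plants (-0.40 with tomato, against 0.06). Over probe sets chosen by their mean of 6 arrays, the median increment was 0.0388% of the T34 level at log2 levels of 12 to 14 and 0.260% at 14 to 17, a ratio of 6.72 (bootstrap interval 4.15 to 10.1). This is over the bound of 4 set in advance, but members went both ways (quartiles of -0.538% to 0.199% and -0.336% to 0.774%), so the ratio does not decide on RNA of T34. By ranks on the unnormalized intensities, again centred on array medians, 27.2% of T34-bright members had every array without plants above every tomato array. The share was 1.70% of T6-bright members chosen the same way on RMA values. Most T34-bright members did not show this order, and ranks were tested for this choice of members only. The ranks therefore argue against normalization only for a part of the members chosen as near background with tomato. The test set in advance did not decide, at 0.16 between bounds of 0.1 and 0.2. RNA of T34, transcripts of T87 that are lower with plants, and normalization for the other members stay open.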

How the results depend on the processing

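All alternatives were fixed before the data were examined, except leaving out probe sets over 8 times brighter in another strain. Counts were compared within 1.5 times. The 16 named changes kept their direction in all 186 alternatives run for them and their call in 181; the other 5 are falls in T7. Most of these directions could not have turned. Named probe sets were chosen with every tomato array on the same side of the other arrays, so leaving out an array cannot reverse them. The series table, the joint fit and the fit without probe sets over 8 times brighter in another strain return the same log2 changes. Direction was therefore tested mainly by the unnormalized table, where all 16 kept it. A second quantile normalization, the filter on dim probe sets, other estimates of spread and array weights were not run for them. Without an intensity trend T7 had 7 calls against 126, and whether its named changes keep their call there was not tested. Median centring and the joint fit of all arrays leave the log2 changes nearly or exactly as they were. The sizes of the named changes did not hold. On the unnormalized table after quantile normalization all 16 were smaller, at 20.9% to 90.8% of the log2 change on RMA values. Of these, 6 were under 50%. With normexp they were at 35.8% to 92.4%. Of 142 alternatives of the counts and overlaps, 82 stayed within 1.5 times. The series table equals the main input, so that alternative says nothing about stability. Named probe sets that are themselves over 8 times brighter in another strain have no value under the alternative that leaves those out. List tests were not run because no list could be matched. The cause of the shifts below was not tested, apart from fewer probe sets in the stricter thresholds and filters.

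With 1 array left out the counts ranged from 3863 to 6037 in T34, 22 to 176 in T7, 1390 to 5778 in T87 and 303 to 919 in T6, and from 3937 to 7261 for the interaction. With adjusted p under 0.01 they were 3150 in T34, 27 in T7, 1312 in T87, 266 in T6 and 2602 for the interaction, and with at least 2-fold 1616, 77, 986 and 460 in the 4 strains. The unnormalized table after quantile normalization gave 756 in T7, 4056 in T87 and 9422 for the interaction, and with normexp 772, 4048 and 8340. A fit of all 24 arrays gave 2889 in T34 and 1500 in T7. Without an intensity trend T7 had 7. Array weights gave 220 in T7, 4158 in T87, 1998 in T6 and 9359 for the interaction. Only probe sets above the median level gave 2892 for the interaction. Without probe sets over 8 times brighter in another strain, T34 had 2853 and the interaction 472.

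Of calls shared by 2 strains, the unnormalized table gave 127 for T34 and T7, 1177 for T34 and T87, 117 for T34 and T6, 121 for T7 and T87 and 18 for T7 and T6. The fit of 24 arrays gave 116, 229, 26, 136 and 38 for the same pairs. At least 2-fold in both gave 17 for T34 and T7, 65 for T34 and T87, 6 for T34 and T6, 16 for T7 and T87, and 32 for T87 and T6. The filter on level gave 50 for T87 and T6. Without probe sets over 8 times brighter in another strain the counts were 19 for T34 and T7, 303 for T34 and T87, 22 for T34 and T6, 8 for T7 and T87, and 15 for T87 and T6.

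The share of calls that were higher was 57.7% in T34, 64.3% in T7, 43.2% in T87 and 45.8% in T6. The unnormalized table moved it to 48.1% in T7 and 62.5% in T6, and with normexp to 48.5% and 63.2%. Median centring gave 37.2% in T6. The fit of 24 arrays gave 71.0% in T34, 48.7% in T7 and 31.5% in T6. No scaling moved the median change of all probe sets by over 0.1 on the log2 scale. Each scaling evens out the arrays, so this says little about stability. Median centring in T6 moved that median by -0.037 and the share of higher calls from 45.8% to 37.2%. Signal over background is the limit for dim probe sets.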

Other observations

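The test of neighbouring models and the test of sequence difference were set before their results were seen, and the correlation of rises was chosen after.

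The 8 probe sets with code S34 that were near background in every strain without plants kept a similar order of rise in T34 and T7 (across probe sets, which are not independent replicates: Pearson r = 0.853, exact permutation p = 0.00446; Spearman 0.857, exact permutation p = 0.0107, n = 8). RNA of 1 source that came with the plants may account for this, as may induction of fungal transcripts that both strains share, and the correlation does not separate them. Among 485 other probe sets with codes S34 or T34 in the same range in T34 with tomato, 41 (8.45%) were as bright in T7, which is above the bound of 5% set in advance for excluding fungal transcripts and below the 20% set for their being ordinary. The files name none of the 8, so tomato RNA and fungal transcripts cannot be told apart here.

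Of 753 adjacent pairs among 2623 T87 gene models numbered along scaffolds, of which 213 models were called, 8 pairs were called the same way, against 2.53 in shuffles (p = 0.0041 by permutation, adjusted p = 0.0123 over 3 tests). The same test gave 2 pairs against 0.968 in T6 (permutation p = 0.256, adjusted 0.256) and 10 against 7.53 for VIRENS models in T34 (permutation p = 0.224, adjusted 0.256). No run was longer than 2 models. The order rests on the numbers in the model names. Over all adjacent pairs in T87 the changes correlated weakly (Spearman 0.160, across gene models). That a few neighbouring T87 genes respond together is a hypothesis.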
